A study of Mus musculus with 6 samples.

How the data were processed

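Mouse retinal cells were profiled by RNA-seq of polyadenylated RNA. Per the labels, eyes of mice that were 3 to 4 weeks old at the start received an adeno-associated virus (AAV) carrying either PLAP, the control cargo (AAV-Control), or Sox11 (AAV-Sox11), and the optic nerve was crushed 3 days before the tissue was taken, 2 weeks after the virus. Retinas were dissociated with papain, stained for the surface protein Thy1 and for dead cells, and the live Thy1-positive cells were sorted by flow cytometry. Each library came from 3 retinas of 3 animals, and each group had 3 libraries, named A, B and C. A p-value here therefore rests on the spread between pools of animals, part of which is missing from the deposited values, as described below. The series description says that the control and Sox11 preparations of a replicate were made on the same day. Amplification and library kits for very low input were used, per the labels.

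The submitters' processing notes name CASAVA 1.8.2, edgeR with no version, and the mouse build mm10. The aligner, the read counter, the strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of 26691 Ensembl transcript rows that holds, per library, a column of whole numbers, a column of normalized values, and the authors' own comparison. Every row reached a highest value of at least 1.06 CPM in some library and no value was 0, so the table had been filtered before deposit. Of the rows, 357 carried no gene name, and these held between 0.422% and 0.517% of each library's total.

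The deposited whole-number columns carry no unit in their headers and are treated as a score, that is, as adjusted values rounded to whole numbers, for a reason found in the values. After each transcript's mean log value was subtracted, 6 libraries leave 5 directions in which they can differ, and only 4 of these had any spread beyond rounding. Along the remaining direction, the SD over transcripts of mean value above 2000 was 9.48e-05 natural log units, against 9.18e-05 from rounding alone and 0.017 from read counting alone. In 6 bins of abundance, read counting alone would have given an SD 10.1 to 179 times the SD found. A component across libraries had therefore been taken out on the log scale before deposit, and no header or label records how. AAV-Sox11 B carried 57.7% of the squared weight of the removed direction, AAV-Sox11 A 18.4%, AAV-Sox11 C 12.5%, AAV-Control C 6.37%, AAV-Control B 5.04% and AAV-Control A 0.00272%. Its cosine with the contrast of the groups was -0.019, so the direction left without spread lay almost wholly within groups. Replicate spread along it is missing from the values, and how far this narrowed the spread of each gene was not measured. Since the way of removal is not recorded, the component taken out may also have differed between the groups. Whether the fold changes were altered was not tested. The normalized columns, a signal that the authors deposited beside the whole numbers, equal these times 1 factor per library (0.9649 to 1.043), to within 0.027% for rows above 1000. The deposited log2 fold changes and p-values of the authors are given separately, always named as theirs.

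Because the values are not read counts, the count-based test planned for counts was replaced by the test planned for normalized values, limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1), with no covariate and with Benjamini-Hochberg adjustment over all genes. Unit, test and summing to genes were settled after the values, and trial fits on them, had been seen; the test itself and its covariates were written down before the data were examined. The planned count-model alternatives are not reported, for the same reason. Values of transcripts with the same gene name were summed, times the authors' factor, to 15450 genes, of which 10461 rest on 1 transcript row. All 15450 were tested: the planned minimum mean value of 1 removed 0 genes, since the lowest gene mean was 7.19. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Errors given with log2 fold changes are standard errors of the limma fit, and errors of values are SDs over 3 libraries.

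The fit was tested on simulated data with the means and spreads of the 15450 genes and 200 changed genes, in 10 simulations per setting. The changed genes were drawn from the more abundant genes only, so recovery of changes in low genes was not tested. The spreads were those that limma fitted to the deposited values, from which a direction had already been removed. With independent spread, 5.46% of calls were false, and 74.4% of 2-fold and 98.7% of 4-fold changes were recovered. When 1 within-group direction was then removed from the simulated values, as in the deposited ones, 13.3% of calls were false, and 6.56% with the direction as a covariate. When the simulated libraries also shared a common factor that the removal took out within groups, 79.1% of calls were false, and 70.9% with the covariate. The covariate is therefore reported beside the counts of calls, and it does not cover the last case.

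Gene lists (38, written before the data were examined) were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were measured, which held for 36 lists, with adjustment over these. They cover ganglion cells and their subtypes, axon injury, stress and apoptosis, immature neurons, progenitors, cell cycle, axon guidance, synapses, ion channels, tubulins, Kruppel-like and Sox factors, immediate early, heat shock, interferon, antigen presentation, ribosomal, respiratory and cholesterol genes, and markers of other cell types of eye and blood. Genes named in the text are Sox11; the 8 largest rises and 8 largest falls among genes past the threshold, with an established name, a mean CPM of at least 5 and the same direction in all 3 same-day pairs; up to 3 members of smallest p per list; the 2 most abundant members of each list of another cell type; 12 genes fixed by name for optic nerve regeneration or kinship to Sox11; and members of groups of 5 or fewer calls. Some genes that this rule names are not reported here. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, where 151 of 152 named genes were found by name.

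Letters A, B and C pair the libraries by the stated shared day. As a check, deviations from the group means were correlated over genes within a letter at 0.00 for A, 0.79 for B and 0.24 for C, while control C and Sox11 B had -0.88, values that the removed direction also shapes. Alternatives covered the replicate block, 3 other scalings, voom weights, a stricter filter, robust variance, other thresholds and pseudocounts, and leaving out each library and each letter. Added after seeing the data were the removed direction as a covariate, alone and with the block, a sex index as a covariate (the mean log2 value of Ddx3y, Eif2s3y, Kdm5d and Uty minus that of Xist, centred), transcript rows in place of genes, genes with 1 row only, and camera's estimated correlation in the fits with libraries left out or a covariate.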

Results

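Sorted Thy1-positive cells from mouse retinas were profiled by RNA-seq 3 days after optic nerve crush, in 3 libraries that had received AAV-Sox11 and 3 that had received AAV-Control. Thy1 is a surface protein of retinal ganglion cells, the neurons whose axons form the optic nerve, and Sox11 is a transcription factor of developing neurons. The comparison asks which transcripts differ in these cells when Sox11 is supplied by the virus. Deposited values summed to between 10747985 and 11546892 per library, and 15450 named genes were tested. These totals are of adjusted, rounded values, so they stand for depth only approximately.

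The sorted cells held abundant transcripts of several retinal cell types. Gnat1, the alpha subunit of rod transducin, had scaled values of 14530 ± 3850 in the controls and 10550 ± 2700 with AAV-Sox11 (SD, n = 3). Gad2, a GABA-synthesizing enzyme of amacrine cells, had 8573 ± 1910 and 10120 ± 1290, and Dkk3, from the list of Muller glia genes, 37420 ± 9260 and 39200 ± 3830. Over controls A, B and C, Dkk3 had 41514.4, 43932.9 and 26816.8. It did not follow the mean of its list there (0.9, -0.43 and -0.48 on the log2 scale), so it may not stand for Muller glia alone. The ganglion cell gene Rbpms, singled out after its values were seen, had 42.44 ± 12.9 and 41.85 ± 1.41, and Thy1 itself 2303 ± 690 and 2908 ± 323. Rbpms was among the low genes of the ganglion cell list, with a mean CPM of 3.764. Some of that list were lower, and others were far higher, such as Stmn2 (63.1) and Slc17a6 (158.8). Spearman correlations over genes were 0.983 to 0.994 between AAV-Sox11 libraries, 0.964 to 0.973 between controls and 0.958 to 0.983 across the groups. The AAV-Sox11 libraries carried most of the weight of the removed direction (57.7%, 18.4% and 12.5% for B, A and C). Their higher correlations and smaller SDs therefore cannot be read as pools that were more alike. The first principal component, with 43.5% of the variance, placed the controls at -35.51, -6.88 and -38.17 and the AAV-Sox11 libraries at 22.08, 34.15 and 24.33. The fifth component held 0.0421%, since 1 direction across the libraries had been removed from the values before deposit.

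**Figure D1:**
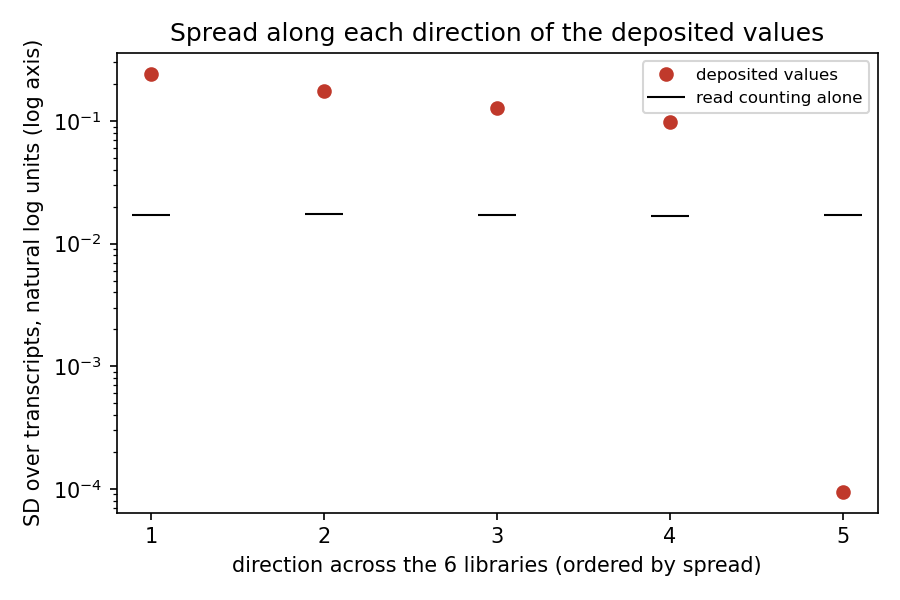
Spread of the deposited values over 1177 transcripts of mean value above 2000 along each of the 5 directions in which 6 libraries can differ (points, SD in natural log units, log axis), and the SD that read counting alone would give (bars). The first 4 directions have SDs of 0.242 to 0.098, and the fifth has 9.48e-05, against 0.017 from counting.

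Sox11 was about 2-fold higher with AAV-Sox11, from 114.1 ± 15.6 to 232.2 ± 52.1 (SD, n = 3). The control libraries A, B and C had 131.1, 110.8 and 100.3, and the AAV-Sox11 libraries 179.3, 233.7 and 283.6, so that all 3 lay above all controls. Sox11 expression had a log2 fold change of 1.003 ± 0.197 (SE), and its limma adjusted p of 0.0503 did not pass 0.05. It was 0.122 with the removed direction as a covariate, 0.229 with the sex index, where the log2 fold change was 0.59, and 0.0447 to 0.278 over all alternatives. Median-of-ratios scaling, upper-quartile scaling, library size alone, the stricter filter and robust variance brought it past the threshold, at 0.0489, 0.0479, 0.0461, 0.0474 and 0.0447. The gene has a single exon on chromosome 12 (27334264 to 27342574, minus strand), and the table has 1 transcript of it, ENSMUST00000079063. Viral and endogenous Sox11 transcripts were not told apart. In the authors' deposited table its log2 fold change was 1.02, with a false discovery rate of 0.00134.

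The largest rises were those of Cd24a, Grap2, Zap70 and Dcx. Cd24a, a surface glycoprotein of immature neurons, rose 6.94-fold in the fit, from 222.7 ± 105 to 1417 ± 225 (SD, n = 3, adjusted p = 0.0201). Dcx, the microtubule-binding protein doublecortin of migrating neurons, rose 3.46-fold, from 102.9 ± 32.3 to 349.7 ± 68.7 (adjusted p = 0.0247). Grap2 and Zap70, an adaptor and a tyrosine kinase of T-cell receptor signalling, rose 6.44-fold and 5.12-fold (log2 fold changes 2.69 ± 0.34 and 2.36 ± 0.34, SE, adjusted p = 0.0169 and 0.0219). The other largest rises were those of Lhx9, a LIM-homeodomain transcription factor (1.54), St8sia4, which builds polysialic acid (1.54), Slc25a24, a mitochondrial ATP-Mg/phosphate carrier (1.52), and Ahnak2 (1.41). All 8 were higher in each of the 3 same-day pairs. With the sex index as a covariate the log2 fold change of Dcx went from 1.79 to 1.11, that of Lhx9 from 1.54 to 0.95 and that of Ahnak2 from 1.41 to 0.85.

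The largest falls included those of Spink10 and Spink13, named for a family of serine protease inhibitors, with log2 fold changes of -1.59 ± 0.15 and -1.49 ± 0.19 (SE, adjusted p = 0.0132 and 0.0171). Their annotated spans overlap on opposite strands of chromosome 18 (62548911 to 62668070 and 62607535 to 62741387), and the strand setting of the counting is not given, so reads of the pair may not be separate. Spink10 also overlaps Spink7 on the opposite strand. Kl, which encodes the ageing-linked protein klotho, fell from 479.3 ± 60.9 to 187.5 ± 29.3 (SD, n = 3, log2 fold change -1.35 ± 0.15, SE, adjusted p = 0.0153). Fam131c (-1.42), Kcnh1, a voltage-gated potassium channel (-1.34), Ces1a, a carboxylesterase (-1.32), Micalcl (-1.31) and Cfap46, a protein of cilia (-1.30), made up the 8, all lower in each same-day pair. Kcnh1 overlaps Hhat on the other strand, and Cfap46 overlaps Gm4459 on its own strand. The values of Kcnh1 rest on 1 transcript row, ENSMUST00000151152, with 3 exons, so other transcripts of the gene are not covered. How reads shared between near-identical copies were counted is not given in the sources used here, which leaves Ces1a, of a family of similar carboxylesterases, and Cd24a, which has related pseudogenes, uncertain to that extent.

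Cd24a lies on chromosome 10 (43578284 to 43584265, plus strand), Grap2 on 15 (80572594 to 80652854, plus), Zap70 on 1 (36761798 to 36782818, plus), Dcx on X (143855842 to 143933311, minus) and Kl on 5 (150952607 to 150993817, plus), in GRCm38. Each is an annotated protein-coding gene, and the table has 1 spliced transcript of each.

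**Figure D2:**
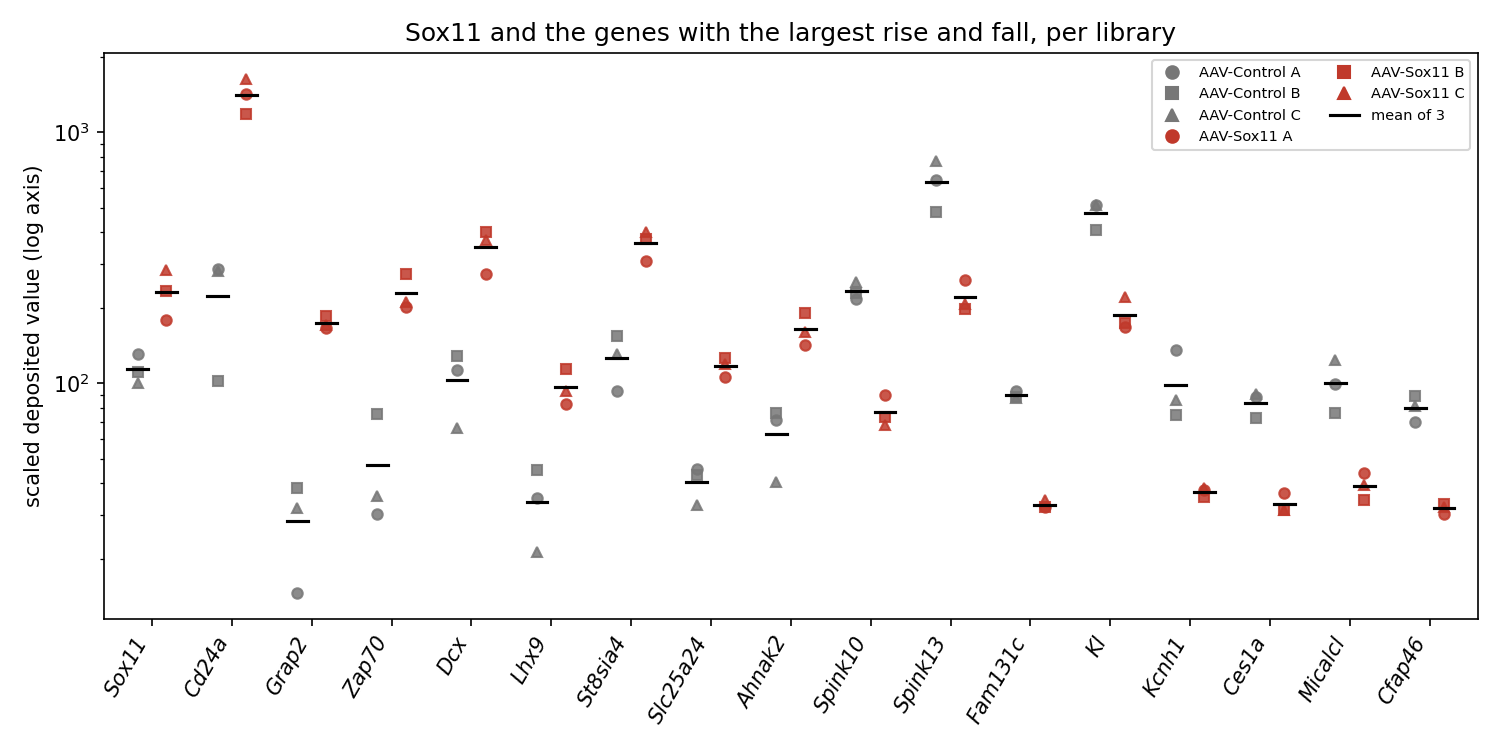
Scaled deposited values (log axis) of Sox11, of the 8 genes with the largest rise and of the 8 with the largest fall, in each control library (grey) and AAV-Sox11 library (red), with bars at the mean of 3. Cd24a moved from a mean of 222.7 to 1417, and Kl from 479.3 to 187.5, with no overlap between the groups.

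In all, 123 genes were higher and 235 lower at an adjusted p under 0.05, of which 46 and 88 differed at least 2-fold. Predicted-gene names made up 20.7% of the genes tested, 8.13% of those that rose and 25.5% of those that fell. An unadjusted p under 0.05 was found for 3762 genes (24.3%). In simulations with 1 direction removed, 9.24% of unchanged genes had such a p, and 16.6% where the libraries also shared a factor, and the 9 other splits of the 6 libraries gave 0 to 1395 genes. In 4737 genes (30.7%, against 10% by chance with 3 against 3) the 3 values of each group did not overlap, and in 0 to 2515 in the other splits. The 10% holds only for libraries that can be exchanged, and the removed direction lay almost wholly within the real groups. Missing spread can therefore favour the real split, and neither the 10% nor the other splits are a fair base for it. With the replicate block, the counts were 323 higher and 414 lower. Of genes higher in AAV-Sox11 and genes lower, 0 and 0 passed in limma with the removed direction as a covariate, where 2583 had an unadjusted p under 0.05, and with block and direction together 56 rose and 62 fell. The sex index as a covariate also gave 0 and 0, with 2705 at an unadjusted p under 0.05. Leaving out AAV-Sox11 A, B or C left 0 calls in limma, with 3121, 1942 and 2956 genes at an unadjusted p under 0.05. Leaving out both libraries of A, B or C left 1, 1 and 0 calls, with 2996, 2017 and 3093. Leaving out control A left 51 and 87, control B 338 and 406, and control C 185 and 210. Upper-quartile scaling gave 100 higher and 355 lower, so that 22.0% of calls were higher, against 34.4%; library size alone gave 103 and 356 (22.4%).

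Among 28 measured genes of immature neurons, 4 rose and 0 fell: Cd24a, Dcx, Dpysl3, a collapsin response mediator (log2 fold change 0.88 ± 0.16, SE, adjusted p = 0.0425), and Stmn2, a tubulin-binding growth cone protein (1.04 ± 0.20, adjusted p = 0.0447). With the sex index as a covariate their log2 fold changes were 0.48 for Dpysl3 and 0.57 for Stmn2. Adjusted over the list alone, 8 rose and 2 fell. The other 24 did not pass over all genes, among them Sox4 (-0.31 ± 0.20) and Sox12 (-0.58 ± 0.26), the close relatives of Sox11. The median over the list was 0.08, with a camera adjusted p of 0.465, and it was 0.21 without control A, -0.02 without control C and -0.05 with the sex index. Library means of the list did not overlap between the groups (0.06, -0.05 and -0.01 in the controls, 0.11, 0.2 and 0.31 with AAV-Sox11).

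Of 23 measured retinal ganglion cell genes, Stmn2 rose, and Ebf1 and Ebf3, transcription factors, fell (log2 fold changes -0.82 ± 0.11 and -1.08 ± 0.19, SE, adjusted p = 0.0204 and 0.0392). The sorted cells held transcripts of several retinal cell types, so these changes need not lie within ganglion cells. Adjusted over the list alone, 5 rose and 2 fell. The list median was 0.37 (camera adjusted p = 0.606), with 0.20 without control C, 0.58 without control B and 0.06 without both libraries of C. With the sex index as a covariate it turned negative, at -0.15. Slc17a6, the vesicular glutamate transporter of ganglion cells, had 1188 ± 277 and 2404 ± 765 (SD, n = 3, adjusted p = 0.0802), and Pou4f2, a transcription factor of ganglion cells, 21.76 ± 10.9 and 58.57 ± 11.3 (adjusted p = 0.0668, and 0.0383 with the replicate block); both were named after their values were seen. None of the 5 measured alpha ganglion cell genes passed (0 over all genes, and 2 higher adjusted over the list alone). Nefh, the heavy neurofilament, had a log2 fold change of 0.77 ± 0.16 (SE, adjusted p = 0.0568, and 0.0381 with the replicate block), Il1rapl2 0.83 ± 0.25 and Calb2 -0.26 ± 0.13. The median of these genes was 0.01 (camera adjusted p = 0.756), and it was negative under other scalings, down to -0.06. It was -0.21 without control A and 0.38 without control C. Library means of the alpha list were narrowly apart (0.11, -0.12 and 0.01 in the controls, 0.14, 0.12 and 0.16 with AAV-Sox11).

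In the list for intrinsically photosensitive ganglion cells, 1 of 6 measured genes, the growth factor gene Igf1, fell (-0.59 ± 0.09, SE, adjusted p = 0.027). Igf1 had a mean CPM of 467.4, against 1.828 to 9.398 for the other members, so it may not stand for these cells alone. Eomes, a transcription factor of these cells, had 1.16 ± 0.25 (adjusted p = 0.0561, and 0.0445 with the block). Adjusted over the list alone, 1 rose and 1 fell. Of 15 genes of other ganglion cell subtypes, Penk, the enkephalin precursor, rose (1.15 ± 0.17, SE, adjusted p = 0.0241) and Sdk2, an adhesion molecule of retinal synapses, fell (-0.52 ± 0.09, adjusted p = 0.0389), and 2 rose and 4 fell adjusted over the list alone. The camera adjusted p of these lists was 0.759 and 0.625, both with a lower direction. Their medians were -0.02 and -0.11, and their means 0.05 and 0.01. Sdk2 was the most abundant of its list, with a mean CPM of 303.1 against 89.7 for the next. It too may not stand for ganglion cells alone.

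None of the 20 measured genes of axon injury and regeneration passed (0 over all genes, and 2 higher adjusted over the list alone, median 0.23, camera adjusted p = 0.465). The median was 0.10 without control B, 0.13 without AAV-Sox11 C and -0.13 over the axon injury and regeneration-associated genes that no other list holds. Gap43, the growth-associated protein, had 211 ± 35.3 and 346.6 ± 37.6 (SD, n = 3, adjusted p = 0.0561), Lifr, a cytokine receptor, a log2 fold change of 0.43 ± 0.10 (SE) and Basp1 0.48 ± 0.15. Of the 11 measured among the 12 genes fixed by name, only Dcx passed. Socs3 (log2 fold change -0.84 ± 0.37, SE), Stat3 (-0.63 ± 0.28), Klf4 (-0.12 ± 0.40), Klf9 (-0.23 ± 0.14), Igf1r (-0.27 ± 0.09), Lin28a (-1.41 ± 0.38) and Lin28b (-0.29 ± 0.46) had adjusted p-values between 0.0871 and 0.882. Myc was not analysed here.

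Of 28 measured voltage-gated channel genes, 5 fell and 0 rose: the calcium channel subunits Cacna2d3 (-0.76 ± 0.07, SE, adjusted p = 0.0132), Cacna1g (-0.64) and Cacnb4 (-0.74, adjusted p = 0.0493, and 0.0513 with the replicate block), the potassium channel Kcnb2 (-0.58) and the sodium channel Scn1a (-0.70). Adjusted over the list alone, 10 fell and 4 rose, and the camera adjusted p was 0.059. The voltage-gated ion channel genes passed as a list without control C, at 0.0151, without AAV-Sox11 B, at 0.0366, and with the sex index, at 0.0283. With an estimated correlation the adjusted p was 0.887 over all libraries, and no list passed in any of these 3 fits. Of 36 synaptic genes, Sv2b, a synaptic vesicle glycoprotein (-1.02 ± 0.17, SE, adjusted p = 0.0313), and Glra2, a glycine receptor subunit (-0.40 ± 0.07, adjusted p = 0.0448), fell and none rose; 8 fell and 1 rose adjusted over the list alone. The synaptic list had a median of -0.24 (camera adjusted p = 0.00256, adjusted p = 0.887 with an estimated correlation, which was 0.03). Library means of the synaptic list did not overlap between the groups (0.13, -0.08 and -0.04 in the controls, -0.28, -0.24 and -0.16 with AAV-Sox11). Nor did those of the voltage-gated list, which had no camera call over all libraries (0.07, 0.03 and -0.1, and -0.14, -0.12 and -0.22). The bipolar and rod lists also had lower medians with AAV-Sox11 (-0.76 and -0.48), but their library means overlapped between the groups, although they were lower in each same-day pair. Library means without overlap were not particular to the synaptic and voltage-gated lists. Immature neuron, alpha ganglion cell and tubulin genes, higher with AAV-Sox11, and oligodendrocyte genes, lower, also had them, with no camera call.

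Of 24 measured genes of the integrated stress response and apoptosis, 1 rose, Bcl2l11, which encodes the cell death protein Bim (916.8 ± 83.8 to 1571 ± 251, SD, n = 3, adjusted p = 0.038), and 21 of the 24 had a positive log2 fold change. The same 1 rose adjusted over the list alone. With the sex index as a covariate its log2 fold change went from 0.77 to 0.46, and the list median was 0.11 (adjusted p = 0.103). The median was 0.27 (camera adjusted p = 0.0177, adjusted p = 0.924 with an estimated correlation). Library means of the list did not overlap between the groups (-0.01, -0.03 and 0.03 in the controls, 0.21, 0.3 and 0.42 with AAV-Sox11). The integrated stress response and apoptosis genes did not pass without control B, at 0.051, or without AAV-Sox11 C, at 0.0585, and had a median of 0.15 without both libraries of C. Phgdh, of serine synthesis, had 1.38 ± 0.47 (SE, adjusted p = 0.134, and 0.0448 with the block). Of 16 progenitor and neurogenic genes, 2 fell, both over all genes and adjusted over the list alone: Pax6, which adult amacrine cells also express (-0.60 ± 0.08, SE, adjusted p = 0.0219), and Neurod4, which adult bipolar cells also express (-0.77 ± 0.15, adjusted p = 0.0467). That list had a median of -0.60 (camera adjusted p = 0.0197, adjusted p = 0.924 with an estimated correlation), and -0.25 with an adjusted p of 0.333 without control A. Library means of the progenitor list overlapped between the groups (0.48, -0.28 and -0.20 in the controls, -0.23, -0.38 and -0.53 with AAV-Sox11), as did those of the bipolar list, although both lists were lower in each same-day pair.

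Rod, cone and bipolar lists had negative medians, passed camera at its preset correlation, and did not pass with an estimated correlation. None of 18 rod genes passed singly, and 17 had a negative log2 fold change (median -0.48, camera adjusted p = 0.000856, adjusted p = 0.924 with an estimated correlation). Sag, rod arrestin, had -0.66 ± 0.16 (SE, adjusted p = 0.0707, and 0.0285 with the replicate block), and Gnat1 -0.46 ± 0.24 (adjusted p = 0.288, and 0.0345 with the block). All 9 cone genes (median -0.77, camera adjusted p = 0.0197) and all 14 bipolar genes (median -0.76, camera adjusted p = 0.00315) were on the lower side, none past the threshold singly, and both lists had an adjusted p of 0.924 with an estimated correlation. Adjusted over the list alone, 0 rod, 0 cone and 4 bipolar genes fell. Grik1, a glutamate receptor of OFF bipolar cells, had 890.9 ± 667 and 173.3 ± 39.4 (SD, n = 3), adjusted p = 0.0838, and 0.0345 with the block, while Prkca, a marker of rod bipolar cells, had 5844 ± 521 and 5580 ± 302. The list means were lower with AAV-Sox11 in each same-day pair, with differences of -0.38, -0.44 and -0.56 for rods in A, B and C, -1.21, -0.18 and -0.78 for cones, and -1.57, -0.22 and -0.75 for bipolar cells. Control A stood apart: its bipolar list mean was 0.98 above the control mean on the log2 scale, against -0.69 and -0.29 in controls B and C and -0.59, -0.91 and -1.03 with AAV-Sox11. Without control A, the bipolar median was -0.28 (camera adjusted p = 0.126), the cone median -0.30 (0.173) and the rod median -0.37 (0.0317). The cone photoreceptor genes also did not pass without AAV-Sox11 C (median -0.56, adjusted p = 0.0774) or with the sex index (-0.57, adjusted p = 0.123). The rod photoreceptor genes had a median of -0.26 without AAV-Sox11 C, and the bipolar cell genes of -1.20 without control B.

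Of 15 amacrine cell genes, 3 fell: Lgr5, a receptor of Wnt-related signalling (6492 ± 248 to 3595 ± 63, SD, n = 3, adjusted p = 0.0113), Pax6, and Slc6a9, a glycine transporter (-0.93 ± 0.18, SE, adjusted p = 0.0481). The other 12, among them Gad2 (0.25 ± 0.17), did not pass, and the list median was 0.33 (camera adjusted p = 0.939, 3 fell and 1 rose adjusted over the list alone). That median was 0.51 without control A, 0.16 without control C and -0.11 with the sex index. Muller glia genes had a median of -0.06 over 13, with 0 calls both over all genes and adjusted over the list alone (camera adjusted p = 0.625), and their list mean was 0.90 in control A. Their median was 0.27 without control A and -0.27 without control C. Of 21 microglia and macrophage genes, 0 passed in either adjustment (median -0.31, camera adjusted p = 0.0524, 0.00181 with the replicate block, and adjusted p = 0.924 with an estimated correlation), with Tmem119 at -0.82 ± 0.26 (SE, adjusted p = 0.122, and 0.0286 with the block). The median of the microglia and macrophage genes was 0.03 without control C (adjusted p = 0.423) and 0.08 with the sex index (0.815), while the list passed without control B (0.000319), AAV-Sox11 A (0.0447) or AAV-Sox11 C (0.0215), and with block and estimated correlation its adjusted p was 0.927. Of 6 T lymphocyte genes measured, 0 passed in either adjustment (median 0.79, camera adjusted p = 0.34), with Cd4 at 1.28 ± 0.47 and Trac, the T-cell receptor alpha constant region, at 0.65 ± 0.26. The T lymphocyte genes passed as a list without control C (median 1.26, adjusted p = 0.0472), and had a median of 0.35 without control A (adjusted p = 0.596). With an estimated correlation their adjusted p was 0.924.

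**Figure D3:**
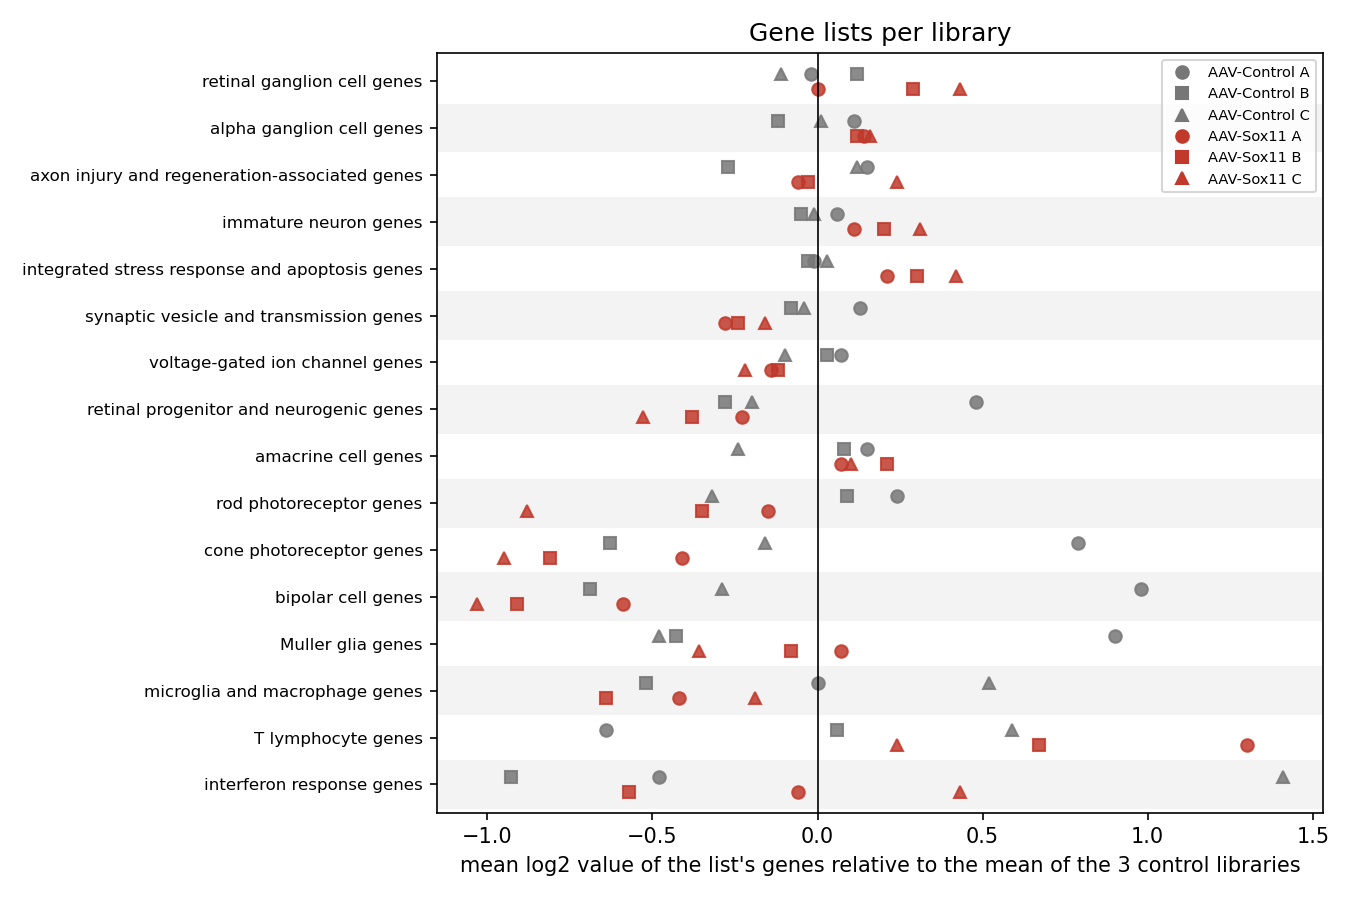
Mean log2 value of the genes of 16 lists in each library, relative to the mean of the 3 control libraries (controls in grey, AAV-Sox11 in red). The bipolar list of control A lies at 0.98 and the interferon list of control C at 1.41, apart from the other controls.

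The other lists had no camera call. For horizontal cells (4 measured, median -0.23, camera adjusted p = 0.595), astrocytes (4, -0.02 and 0.97), endothelium (5, -0.21, 0.756), pericytes and smooth muscle (10, -0.13, 0.756), fibroblasts (3, 0.21, 0.771) and pigment epithelium and melanocytes (3, 0.36, 0.756), no gene passed in either adjustment. Among 4 oligodendrocyte genes (median -0.12, camera adjusted p = 0.34), 0 passed over all genes and 1 was lower adjusted over the list alone. Alas2, an enzyme of haem synthesis and the only erythrocyte gene measured, fell (-1.07 ± 0.19, adjusted p = 0.0425). Of 38 axon guidance and adhesion genes, Nrp2, a semaphorin receptor, fell (-0.70 ± 0.10, adjusted p = 0.0201), and 2 rose and 2 fell adjusted over the list alone (median 0.14, camera adjusted p = 0.759). Their median was 0.24 without control A, 0.04 without control C and -0.07 with the sex index. Unc5c, a netrin receptor, had 0.92 ± 0.20 (adjusted p = 0.0584, and 0.0286 with the block). The values of Nrp2 rest on 1 transcript row, ENSMUST00000126344, with 3 exons, so other transcripts of the gene are not covered.

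No gene passed over all genes among the tubulins (13 measured, median 0.24, camera adjusted p = 0.141, 3 higher adjusted over the list alone, with Tubb5 at 0.61 ± 0.12, and 0.0375 as its adjusted p with the block), the Kruppel-like factors (13, -0.10, 0.771, 1 lower adjusted over the list alone, Klf15 at -1.57 ± 0.33, and 0.0388 with the block) or the immediate early genes (16, 0.08, 0.929, 1 lower adjusted over the list alone, Ier5 at -0.54 ± 0.12, and 0.0339 with the block). Reads of tubulin and ribosomal protein genes can be shared with close copies, so these values are uncertain.

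The remaining lists had 0 calls in either adjustment. They were 6 Sox family genes (median -0.59, camera adjusted p = 0.34, and -0.20 without control A), 14 cell cycle genes (0.29 and 0.34), 17 heat shock genes (0.09 and 0.654), 15 interferon response genes (0.10 and 0.756), 12 antigen presentation genes (0.42 and 0.294), 34 cytosolic ribosomal protein genes (0.15 and 0.0899), 38 nuclear-encoded respiratory chain genes (0.04 and 0.756) and 19 cholesterol synthesis genes (0.21 and 0.0669, and 0.0149 with the replicate block). For the cholesterol list the adjusted p with an estimated correlation was 0.924, and 0.927 with the block. The respiratory median was -0.02 under another scaling. The heat shock list had a mean of -0.05, and the interferon list a mean of -0.07 and a lower camera direction. Without control C, lists of cell cycle genes (0.59, adjusted p = 0.00437), interferon response genes (0.52, 0.00757), antigen presentation genes (0.99, 0.000277), cytosolic ribosomal protein genes (0.28, 8e-05) and cholesterol synthesis genes (0.25, 0.0142) passed. With an estimated correlation no list passed without control C (smallest adjusted p = 0.698). With the sex index as a covariate, lists of cell cycle (0.53, adjusted p = 0.0252), heat shock (0.27, 0.0143), interferon response (1.04, 0.0398), antigen presentation (1.18, 0.00442), ribosomal protein (0.38, 0.000145) and T lymphocyte genes (1.94, 0.00986) passed as higher, and none with an estimated correlation (smallest adjusted p = 0.575). Ribosomal genes also passed without AAV-Sox11 B (0.0257), and cholesterol synthesis genes without AAV-Sox11 A (0.00975) or B (0.0366). Mitochondrially encoded genes were not analysed here.

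Of the 36 lists tested with camera, 6 passed, 5 lower and 1 higher. With an estimated correlation 0 passed (smallest adjusted p = 0.887), also when 1 library or both of a letter were left out (smallest 0.698). This form of camera lost calls even where the correlation was low. That of the voltage-gated list was estimated at 0, under the preset 0.01, yet its unadjusted camera p went from 0.0131 to 0.0493. Not passing it therefore does not show that correlation between genes made the preset calls. Likewise 0 passed with fry, which tests whether the genes of a list move, on balance, 1 way (smallest adjusted p = 0.065), while 14 passed fry's test of change in either direction, which does not compare a list with other genes. Among these 14 were the lists of retinal ganglion cells (adjusted p = 0.00127), alpha ganglion cells (0.0347), axon injury and regeneration (0.0064) and immature neurons (0.000357). The others were both further ganglion cell lists, stress and apoptosis, progenitors, axon guidance, synapses, voltage-gated channels, tubulins, immediate early genes and amacrine cells. Of the 30 lists without a call, 13 had a median that changed sign when 1 of the libraries was left out. Leaving out 1 library gave medians of -0.27 to 0.24 for intrinsically photosensitive ganglion cells, -0.50 to 0.31 for astrocytes, -0.48 to 0.16 for endothelium, -0.37 to 0.30 for pericytes and smooth muscle and -0.21 to 0.57 for fibroblasts. The medians were -0.42 to 0.52 for the interferon response, -0.16 to 0.03 for Kruppel-like factors, -0.08 to 0.17 for immediate early genes and -0.01 to 0.08 for the respiratory chain. Without a change of sign they were -0.27 to -0.06 for other ganglion cell subtypes, -0.35 to -0.12 for horizontal cells, -0.19 to -0.09 for oligodendrocytes, 0.07 to 0.61 for pigment epithelium, -0.82 to -0.20 for the Sox family, 0.20 to 0.59 for the cell cycle, 0.09 to 0.99 for antigen presentation, 0.04 to 0.28 for ribosomal proteins, 0.11 to 0.30 for cholesterol synthesis and 0.05 to 0.15 for heat shock genes.

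In the authors' deposited table, 514 transcripts were higher and 1310 lower at a false discovery rate under 0.05, out of 26691, and these belong to 1556 named genes. Of the 358 genes called here, 344 (96.1%) have such a transcript with the same direction. Over transcripts, which are not independent replicates, the deposited log2 fold changes and those fitted here had a correlation of 0.99. Both rest on the same values, so the overlap is not independent evidence. For Cd24a the authors' deposited table gives a log2 fold change of 2.67, for Zap70 2.27, for Dcx 1.76 and for Kl -1.35.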

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

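The removed direction, the sex index, transcript rows, genes with 1 row, and the estimated correlation in other fits were chosen after seeing the data, and the other settings before the data were examined. The unit, the choice between the planned tests and the summing to genes, which the main fit uses, were also settled after seeing the data. No result past its threshold changed direction. The interferon response genes, lower by camera and not past it, passed as higher without control C (median 0.52) and with the sex index (1.04), and leaving out 1 library gave -0.42 to 0.52. A change of sign in a result that passed in neither setting was counted as no change. For genes higher in AAV-Sox11 (123) and genes lower in AAV-Sox11 (235), the replicate block gave 323 and 414, and with median-of-ratios size factors 264 and 427. Upper-quartile factors gave 355 lower and library size only 356. A threshold of adjusted p under 0.1 gave 784 and 816, and at least a 2-fold change 46 and 88. The removed direction as a covariate gave 0 and 0, with the replicate block 56 and 62, the sex index 0 and 0, and genes with 1 transcript row 47 and 91. Transcript rows as deposited gave 390 lower, and with the removed direction 18 and 37. Leaving out 1 library, or both libraries of a letter, gave 0 to 338 genes higher and 0 to 406 lower. Fewer libraries or residual degrees of freedom account for part of these losses by construction; for the rest the cause was not tested. The sex index shares 53.8% of its variance with the groups, which limits what remains to test. Sox11 expression passed with median-of-ratios (0.98), upper-quartile (0.955) and library-size scaling (0.939), a mean CPM of at least 5 (1.003), robust empirical Bayes (1.003), adjusted p under 0.1 (1.003), pseudocount 0.1 (1.01) and transcript rows (1.003) (values are log2 fold changes). Over all alternatives its adjusted p was 0.0447 to 0.278, and its log2 fold change 0.59 with the sex index. Without 1 or 2 libraries its log2 fold change was 0.76 to 1.28. With the replicate block its adjusted p was 0.0566. The 4 lists of ganglion cell, alpha ganglion cell, regeneration and immature neuron genes passed camera in no setting. Both of fry's tests were run on the main fit only, without the removed direction as a covariate. There none of these lists passed its test of a shared direction (smallest adjusted p = 0.0651, for the alpha ganglion cell genes). All 4 passed its test of change in either direction. Over 25 settings, 518 of 907 calls of the 37 named genes past the threshold were kept, 389 were lost, and 0 turned in direction. With the block and removed direction together 11 of the 37 kept their call, Cd24a, Grap2, Zap70, Dcx, St8sia4, Spink10, Spink13, Kl, Ebf1, Cacna2d3 and Lgr5, and 68 of the 118 genes called there are among the 358. The replicate block changed no other call of a result given in the text than those beside which its value stands. Without genes shared with another list, the retinal progenitor and neurogenic genes no longer passed as a list (adjusted p = 0.0813). Among genes with 1 transcript row 0 of the 6 lists passed, which leaves fewer genes per list. The minimum mean value removed 0 genes and so tests nothing. The planned count-model fits are not reported. Read depth cannot be judged from adjusted values, and limits for low genes such as Lin28a (mean CPM 0.896) are unknown.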

Other observations

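The count of splits for lists was planned before its result was seen; the prediction for the count of genes was reworded, and the tests of the removed direction, the sex index and the rod, cone, bipolar and T lymphocyte lists were chosen, after their results were seen. None of the sex-linked transcripts given here passed the threshold. Of the Y chromosome, Ddx3y, Kdm5d and Uty had all 3 AAV-Sox11 values below all 3 controls, with log2 fold changes of -0.73 for Kdm5d (adjusted p = 0.0873) and -1.05 for Uty (adjusted p = 0.0817). The sex index was 0.23, 0.26 and 1.79 in the controls and 0.18, -1.06 and -1.40 with AAV-Sox11. Ddx3y had 1364 ± 588 in the controls and 710.8 ± 131 with AAV-Sox11 (SD, n = 3; log2 fold change -0.87, adjusted p = 0.123), and Xist, expressed from the inactive X, 62630 ± 17200 and 100300 ± 31900 (0.66, adjusted p = 0.211). Of the 358 called genes, 11 (3.07%) lie on X or Y, against 3.54% of genes tested (Fisher's exact test, two-sided, p = 0.772). Interferon response genes were high in control C, at a list mean of 1.41, against -0.48 and -0.93 in controls A and B. Ciita, the regulator of MHC class II genes, had 187.8 ± 91.9 and 485.8 ± 155 (SD, n = 3; adjusted p = 0.0812, and 0.0285 with the replicate block), and Mki67, a proliferation gene, 799.3 ± 829 and 1550 ± 522 (adjusted p = 0.236).

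The 358 calls depend on how the replicate spread is counted. In the 10 splits of the 6 libraries into 3 and 3, the real one gave 358 genes (1 split with as many) and the highest other 0, but 10 splits are too few for a share under 0.05. The spread missing from the values also lay almost wholly within the real groups, which can favour the real split over the others. A direction removed from the values before deposit may have narrowed the spread: with it as a covariate 0 genes passed. The fold changes of the called genes moved by at most 0.0016 (median size 0.83 on the log2 scale in both fits). This was fixed in advance, since the direction lay almost wholly within groups and the values have almost no spread along it. It is therefore no check of the fold changes. The median SE of the called genes went from 0.125 to 0.152. The residual degrees of freedom went from 4 to 3, and the prior ones, which limma adds from all genes, from 3.45 to 4.91. The smallest adjusted p became 0.0579. Which of the called genes would pass on unadjusted reads stays open.

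Rod, cone and bipolar lists had lower medians together, and camera's preset correlation makes such calls easy here: the real split gave 6 lists, all 10 of the 10 splits gave as many, and the highest other split gave 21, which points to a structure of the libraries, and 10 splits are too few for a share under 0.05 (9 to 11 lists in the 3 other splits that part all 3 same-day pairs). Carry-over of photoreceptor and bipolar cells or their RNA that varies between preparations is a candidate explanation. Members of each list varied together within groups (estimated correlations of 0.75, 0.42 and 0.65, the lowest 0.42). Some lists that mark no cell type did so too, such as interferon response (0.91) and ribosomal protein genes (0.43), and others did not, such as synaptic genes (0.03). The correlations therefore do not single out carry-over. The Thy1 gate should remove these cells, yet Gnat1, of rods, had 14530 ± 3850 in the controls (SD, n = 3). A lower share of all other cells would lower amacrine genes as well: their mean minus that of the 3 lists was higher with AAV-Sox11 in each same-day pair (0.96, 0.40 and 1.04, mean 0.80 ± 0.20, SE), which goes against it, but 3 pairs give a 95% interval of -0.07 to 1.67 and no exact sign-flip p below 0.25 (two-sided), and the 3 amacrine genes past the threshold fell, so this cannot be told apart from the first. An effect of AAV-Sox11 on these transcripts stays open too, with a lowest adjusted p of 0.924 with an estimated correlation.

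Zap70 and Grap2 are known from T cells, and mouse T cells carry Thy1, so that the gate would not remove them. More T lymphocytes in the AAV-Sox11 sorts are a candidate explanation. The mean of the 2 genes minus that of the T-cell list was 1.79 ± 0.48 (SE) higher with AAV-Sox11, and all 3 values (1.11, 2.04 and 2.21) lay above the control values (-0.01, 0.60 and -0.59; exact permutation p = 0.1, two-sided, the smallest possible). This excludes nothing, since the 2 genes were picked for their large rise, and of the 20 genes in the list 6 were measured, of which Cd4 and Ccl5 are also expressed by other cells and would hide a small share. More T lymphocytes and expression in retinal cells under AAV-Sox11, which was not tested, both stay open: the T lymphocyte genes passed as a list without control C (median 1.26, adjusted p = 0.0472) and not without control A (0.35, adjusted p = 0.596), with 0.00986 to 0.924 over all alternatives.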
